A study of Rattus norvegicus with 32 samples.

How the data were processed

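DNA from nucleus accumbens punches of 32 rats, about 250 ng each, was processed by the authors for enhanced reduced representation bisulfite sequencing, per the labels' protocols. The submitters' processing notes name CASAVA, Bismark and methylKit and the rat build rn4; versions were not given in the sources used here. Per the file headers, each deposited table lists cytosines with their position, strand, coverage as a count of reads, and the percent of reads with C and with T. The deposited coverage signal and percent values are not normalised, and the product of percent and coverage was a whole number in 100% of lines (within the rounding of the printed percent), so counts of methylated and unmethylated reads were recovered from them. Lines started at a coverage of 1, and the sum of the C and T percent values was never under 90.02, a limit that no label or header records. In the table of VEH female 26_9, 61 lines were damaged and were left out.

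The calls of both strands of a CpG were summed. CpGs needed at least 10 reads in at least 6 of 8 animals of each group, and values above the 99.9th percentile of coverage of a library were dropped. CpGs at most 100 bp apart were joined into regions of at least 3 CpGs and at most 1000 bp, which took in 80.2% of the retained autosomal CpGs. Coordinates are those of build rn4, counted from 1. Each region was tested by logistic regression on methylated and unmethylated counts, with a Pearson dispersion moderated across regions in the manner of the squeezeVar function of limma (3.58.1) and an F test. Regions were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 5 percentage points. Exposure was tested on counts summed per family, since the labels say that the animals came from several mothers and fathers per line. Sex, with exposure as a term, the interaction of exposure and sex, and differences among families within a line (no minimum difference) were tested with the animals as replicates. Average levels were compared by exact permutation of families between lines, or by 100000 permutations of animals between sexes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma and edgeR 4.0.16 for alternatives. Figures were drawn with matplotlib 3.10.9.

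Named regions followed a rule fixed before the data were examined: up to 10 regions per direction called for exposure, up to 10 per direction called with animals as replicates that also had an unadjusted family-level p under 0.05, up to 5 per direction called within a sex or for the interaction, and for sex up to 5 per direction on autosomes and on X. Regions are named by chromosome, start and end because no annotation of build rn4 was used here. For the same reason genes, promoters, exons, gene lists and cell type markers were not analysed here, and classes of average level (under 20%, 20 to 80%, over 80%) and of CpG number took the place of annotated features. The tests were tried on simulated counts with the real coverage and dispersion in which 200 regions with a base level between 35% and 65% were moved by 5, 10, 20 or 30 points. There the share of unchanged regions at an unadjusted p under 0.05 was 6.29% to 6.49% for the family-level exposure test, so unadjusted counts run slightly above the nominal rate.

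Whether the first number of a name marks relatives was checked at 1184 CpGs whose levels clustered near 0, 50 and 100%, as sequence variants do (thresholds set after looking at the data). The mean correlation was 0.734 between animals sharing a number and 0.606 between other animals of the same line (10000 permutations of the numbers within lines, one-sided p = 0.0001, the smallest they can give). The closest animal carried the same number for 27 of the 31 animals that shared a number with another. The numbers were therefore used as families and as a block (paired samples) in alternative fits. No pair of libraries matched within sampling noise: over 33346 intermediate regions the mean chi-square per region was at least 6.85 in each of 496 pairs. Intervals of the exposure difference include the spread between families, and reads without molecular identifiers are not independent molecules.

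Alternatives covered the replicate unit, other tools (limma with family as a random block, limma on family means of logit values with an offset of 0.5, edgeR on family counts), coverage minimums of 20 and 30 reads, CpGs present in all 32 animals, single CpGs, joining distances of 50 and 200 bp, no or a 10-point minimum difference, unmoderated dispersion, plus-strand calls, and leaving out variant-like CpGs, meaning those ranging over more than 50 points, or each family. Added after seeing the data were fits without 6 THC female libraries that had over 55% of cytosines under 10 reads, without 2 libraries that deviated most from the others (VEH female 24_8 and THC male 19_5), with the share of such cytosines as a covariate, and with sexes paired within family for average levels.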

Results

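Enhanced reduced representation bisulfite sequencing reads cytosine methylation next to cutting sites of the restriction enzyme MspI and is enriched for CpG-dense DNA. It was applied to the nucleus accumbens, a part of the ventral striatum with a role in reward, of 32 adult Long-Evans rats at about postnatal day 62. The parents of these rats had received either THC, the main psychoactive compound of cannabis, or saline vehicle (VEH) as adolescents. Each line was represented by 8 female and 8 male offspring. The first number in an animal's name was taken as its family, which gave 5 THC families and 6 VEH families of 1 to 4 animals. The libraries held 213.2 to 292.0 × 10⁶ cytosine calls, and CpGs with at least 10 reads had a median coverage of 103 to 160 reads per library. In all, 1333652 CpGs were covered well enough in every group, 1295616 of them on autosomes and 25590 on the X chromosome. Neighbouring CpGs were joined into 127906 autosomal regions with a median of 4 CpGs, a median length of 88 bp and a median of 727 reads per animal. Of these regions 24.9% were unmethylated (mean level under 20%), 28.0% intermediate and 47.1% methylated (over 80%). Unmethylated regions had a median level of 0.30% and a median of 10 CpGs, whereas methylated regions had a median level of 91.5% and 4 CpGs.

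The comparison of the lines asks whether methylation in the offspring differs with parental THC exposure. THC and VEH families differed little at most regions. The median absolute difference was 0.80 percentage points, and 519 of 127520 tested regions differed by 10 points or more. The 95% interval of the difference lay within 5 points of 0 in 83439 regions (65.4%) and within 10 points in 118517 (92.9%). Among unmethylated regions the share within 5 points was 95.1%, and among intermediate regions it was 25.5%. With families as the replicates, the quasi-binomial test called 0 regions, 7566 regions had an unadjusted p under 0.05, and the smallest adjusted p was 0.177. On the same families, limma called 0 regions with 6137 at an unadjusted p under 0.05, and edgeR called 0 with 6279. With animals and family as a random block, limma called 4 (1 higher and 3 lower in THC, 7445 unadjusted), at an estimated family correlation of -0.0029 that leaves the animals nearly independent in that fit. Of 1287349 single CpGs 6 were called, all lower in THC families (117887 unadjusted), and without VEH family 20 the family-level test called 1 region. In simulated data, 200 regions with a base level between 35% and 65% were moved together. The quasi-binomial test recovered 88.0% of them at 20 points and 21.5% at 10 points. A change in few regions meets a stricter adjusted threshold, so these shares may be too high for it.

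With the 32 animals as replicates, 13 of 120968 regions were called, of which 6 were higher and 7 lower in THC offspring. All 13 had the same sign in females and males, which a choice by a test over both sexes makes likely. Exposure was given to the parents, so single animals are not separate units of exposure. On chromosome 16, positions 54577423 to 54577512 (6 CpGs, build rn4) were methylated at 68.4% ± 2.5 (SD, n = 5 families) in THC and 54.1% ± 5.0 (SD, n = 6 families) in VEH offspring. The animal-level adjusted p there was 0.00094, and the family-level adjusted p was 0.177. The largest difference in the other direction was on chromosome 10, positions 83356780 to 83356831 (4 CpGs), at 44.3% ± 5.5 (SD, n = 5) in THC and 60.3% ± 5.7 (SD, n = 6) in VEH families. On chromosome 9, positions 32776586 to 32776722 (5 CpGs) were at 66.4% ± 1.9 (SD, n = 5) in THC and 75.3% ± 1.8 (SD, n = 6) in VEH families. On chromosome 2, positions 28813517 to 28813654 (4 CpGs) were at 76.2% ± 7.3 (SD, n = 5) in THC and 89.9% ± 4.4 (SD, n = 6) in VEH families. The longest region, on chromosome 10 from 5590396 to 5590760 (22 CpGs), was at 31.8% ± 3.6 (SD, n = 5) in THC and 38.9% ± 1.9 (SD, n = 6) in VEH families. Each of these 5 regions had a median of at least 677 reads per animal. Of the 13 regions, 7 lay on chromosome 10, which held 7.62% of the tested regions (Fisher's exact test, two-sided, p = 1.69e-05, and 0.000338 after Bonferroni adjustment over 20 autosomes). This was tested after it was seen. The test takes regions as independent, but 5 of the 7 lay under 20 Mb and may be linked, so its p-values may be too small. The THC families and the VEH families did not overlap in 6 of the 13 regions. Chance gives this arrangement for 0.433% of regions before any selection, but the 13 were chosen for a difference between the lines, so that share is no comparison for them. At least 1 CpG ranging over more than 50 points between animals was present in 12 of the 13. Without such CpGs, 4 of the 12 regions that could still be measured kept their sign and a family-level unadjusted p under 0.05. Among these 4, the difference was then 15.3 points on chromosome 16, -6.5 in the longest region and an unchanged -8.9 on chromosome 9, where no such CpG was present. The region on chromosome 2 did not hold, at -1.9 points (against -13.7 with all CpGs), and the region at 83356780 could not be measured. Without 6 THC female libraries in which over 55% of cytosines had under 10 reads, which leaves 2 THC females, 5 regions were called, 1 of them among the 13. The family-level differences of the 13 kept their sign there, at 6.7 to 17 points for the 6 higher regions and -16.1 to -6.1 points for the 7 lower ones.

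**Figure D1:**
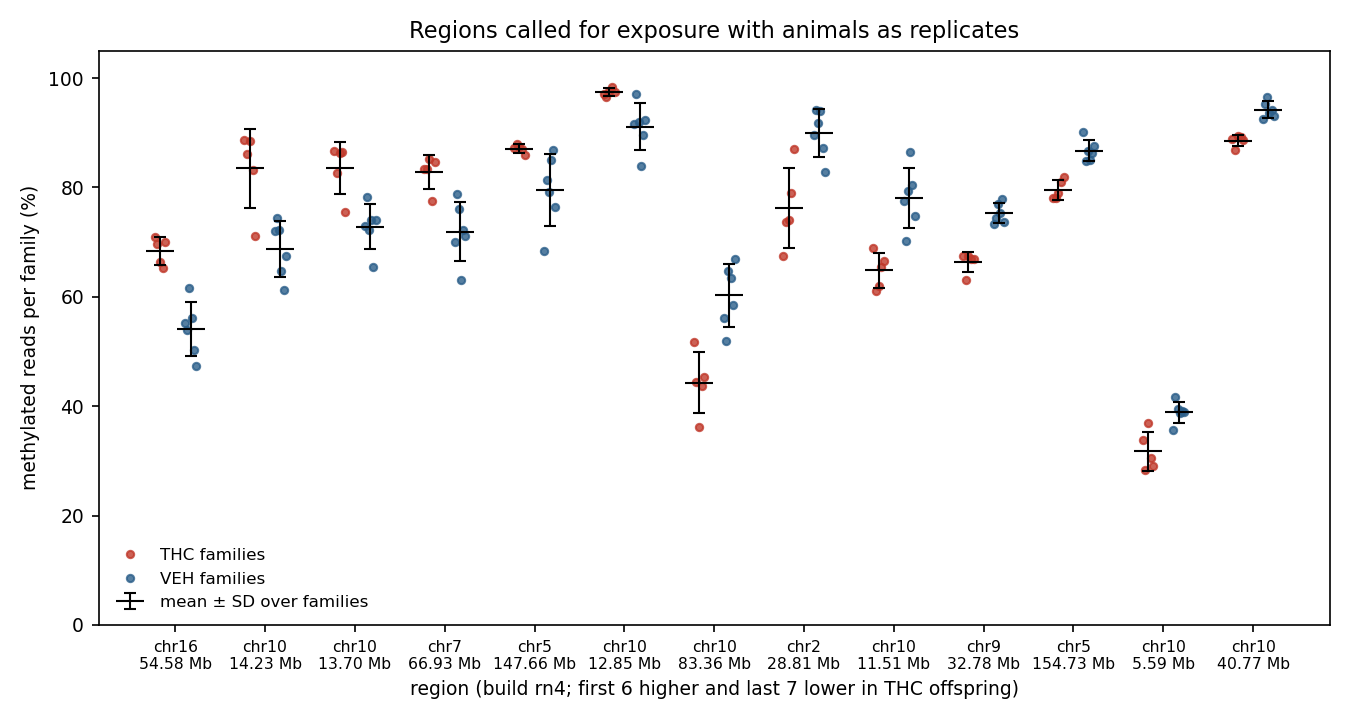
Percentage of methylated reads in each family (points) at the 13 regions called for exposure with animals as replicates, with the mean and SD over 5 THC and 6 VEH families as black bars; the horizontal axis gives the chromosome and the start in Mb. The 6 regions on the left were higher and the 7 on the right lower in THC families, and points of the groups overlap in 7 of the 13.

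Within each sex, the family-level comparison called 0 regions. In females 10378 of 126548 regions had an unadjusted p under 0.05, and the smallest adjusted p was 0.229. In males the corresponding numbers were 7571 of 125984 and 0.136. The quasi-binomial test with animals as replicates called 1 region in females (9463 unadjusted) and 2 in males (7691 unadjusted). The family-level test called 3 regions in females without VEH family 26 and 4 in males without THC family 3. In simulated data, a 20-point change in 200 regions together was recovered in 71.5% of them in females and 49.0% in males. Whether the THC minus VEH difference itself differed between the sexes was tested directly with animals as replicates, and 4 regions passed. In each of them the mean of THC males lay above that of VEH males, and the mean of THC females lay below that of VEH females. On chromosome 12, positions 40245648 to 40245687 (3 CpGs, median 135 reads) were at 83.7% ± 15.7 in THC males and 47.0% ± 12.4 in VEH males, against 62.8% ± 10.7 in THC females and 67.5% ± 12.9 in VEH females (SD, n = 8 each, interaction adjusted p = 0.036). On chromosome 10, positions 37768038 to 37768104 were at 45.2% ± 11.2 in THC males and 25.7% ± 5.5 in VEH males (SD, n = 8 each), and at 43.7% ± 2.6 and 45.9% ± 5.3 in the females. The other 2 regions lay on chromosome 11, at 71211097 to 71211192, and on chromosome 1, at 78380765 to 78380850. With family as a block the quasi-binomial test called 0 regions (7718 at an unadjusted p under 0.05), and at a minimum of 20 reads, where 2 of the 4 could be measured, it called 0 (7283 unadjusted). The THC female libraries stood apart in coverage. The share of cytosines with under 10 reads was 57.7% ± 8.2 in them (SD, n = 8), against 33.1% ± 12.8 in VEH females, 31.4% ± 15.9 in THC males and 37.7% ± 7.0 in VEH males. As family means, this share was higher in THC than VEH females (58.7% ± 5.8 against 34.8% ± 11.3, SD, n = 5 families each, exact permutation test, two-sided, p = 0.00794). With that share as a covariate 0 interaction regions were called (6105 unadjusted), and 0 without the 6 THC female libraries over 55% (5490 unadjusted). Without VEH female 24_8 and THC male 19_5, 2 were called.

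Average methylation did not differ detectably between the lines. Over all autosomal CpGs, 34.98% ± 1.3 (SD, n = 5) of reads were methylated in THC families and 35.2% ± 0.37 (SD, n = 6) in VEH families (exact permutation test, two-sided, p = 0.688). In intermediate regions the levels were 56.9% ± 0.52 in THC (n = 5) and 57.2% ± 0.80 in VEH families (n = 6; exact permutation test, two-sided, p = 0.433). In females the level over all CpGs was 34.0% ± 1.3 in THC and 36.1% ± 1.5 in VEH families (SD, n = 5 each, exact permutation test, two-sided, p = 0.0476, adjusted p = 0.190 over 16 tests). With 5 families against 5 the smallest p is 0.00794, and a lone difference could not reach an adjusted p under 0.127. In males the level was 35.7% ± 1.5 in THC and 34.8% ± 1.0 in VEH families (SD, n = 5 each, exact permutation test, two-sided, p = 0.294), and the difference between the sexes was not tested. The female difference of -2.05 points was -0.329 points as an unweighted mean over CpGs. Without the 6 THC female libraries it was 1.32 points, a value set by 2 THC females, 25_6 at 39.1% and 3_10 at 35.7%, which lie on either side of the VEH mean. Over CpGs of unmethylated regions, THC females were at 1.1% ± 0.042 and VEH females at 1.22% ± 0.086 (SD, n = 5 families each, exact permutation test, two-sided, p = 0.0238, adjusted p = 0.19). This difference of -0.123 points was 0.013 points without those 6 libraries. Across the sexes, CpGs of intermediate regions were less methylated in females, at 56.2% ± 1.4 (SD, n = 16), than in males, at 57.8% ± 1.1 (SD, n = 16; permutation test, two-sided, p = 0.0017, adjusted p = 0.0272). This difference of -1.54 points was -1.07 points without those 6 libraries (adjusted p = 0.508) and missed the threshold as an unweighted mean over CpGs (adjusted p = 0.0714) and without VEH female 24_8 and THC male 19_5 (adjusted p = 0.072). Females were lower in 8 of the 9 families that held both sexes, by a mean of -1.38 points with family as a block (SD 2.15, n = 9, exact sign-flip permutation test, two-sided, p = 0.0898, adjusted p = 0.479); family 16 went the other way.

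**Figure D2:**
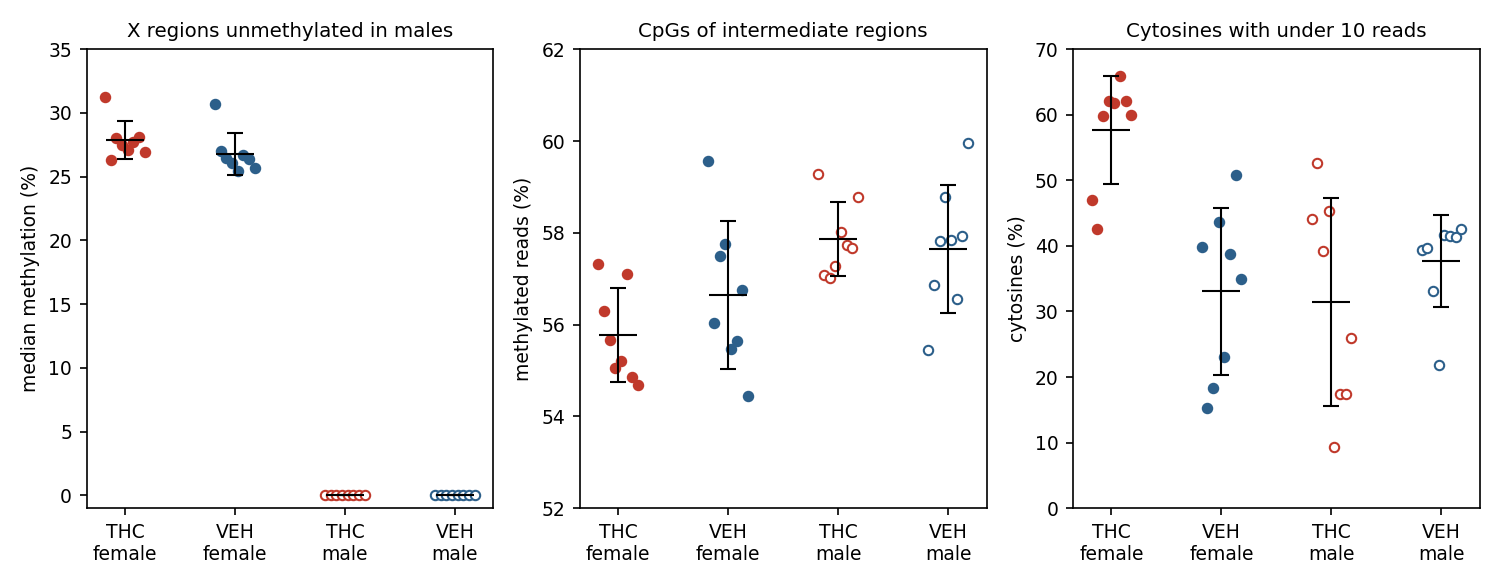
Values per animal (points; filled for females, open for males) with group mean and SD (bars, n = 8) of the median methylation of X regions under 5% in males, the methylated reads over CpGs of intermediate autosomal regions, and the share of cytosines covered by under 10 reads. Females lie between 25.4% and 31.3% on the X measure and all males near 0, and 6 of the 8 THC females exceed 55% on the coverage measure; the middle axis does not start at 0.

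Females and males were compared on the X chromosome, where silencing of 1 copy in females comes with methylation of CpG-dense regions. X regions that were almost unmethylated in males were partly methylated in females. Of 757 tested X regions under 5% in males, 737 were called higher in females, with a median of 27.4% in females and 0.17% in males. Of the 1128 regions over 80% in males, 208 were called lower in females and 2 higher. Over the whole X chromosome 1209 of 2311 regions were called, 964 higher and 245 lower in females, and 1187 were called with family as a block. The largest gain in females was at 52621571 to 52621590 (3 CpGs), with 44.1% ± 9.6 in females and 0.1% ± 0.4 in males (SD, n = 16 each, adjusted p = 1.1e-20). The largest loss was at 137294767 to 137294800 (4 CpGs), with 38.8% ± 11.5 in females and 96.5% ± 3.5 in males (SD, n = 16 each, adjusted p = 1.1e-17). The next 4 losses by size lay between 22727990 and 22784256. The regions under 5% in both sexes numbered 19. Among them, chosen after their values were seen, were 4 neighbouring regions from 16052320 to 16054054, which held 43, 13, 45 and 4 CpGs and stayed at or under 0.7% in females. The median X region had 0.522 times as many reads in males as in females. Per animal, the median over the low X regions was at least 25.4% in each female and at most 0.057% in each male, so the sex label of all 32 animals matched this measure, which rests on regions selected for a low level in males. Among females it did not differ detectably between THC families, at 27.8% ± 1.1, and VEH families, at 27.1% ± 2.0 (SD, n = 5 each, exact permutation test, two-sided, p = 0.5).

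On autosomes, 35 of 120968 regions differed between the sexes, 14 higher and 21 lower in females. The largest gain was at chromosome 9, positions 87327210 to 87327246, with 94.1% ± 1.4 in females and 70.8% ± 3.7 in males (SD, n = 16 each, adjusted p = 5.8e-16). Chromosome 7 held a region at 6228392 to 6228402 with 93.2% ± 2.6 in females and 72.6% ± 5.2 in males, and one at 136296358 to 136296405 with 69.2% ± 4.5 in females and 53.7% ± 4.0 in males (SD, n = 16 each). Further gains were at chromosome 10, 104819300 to 104819342 (76.7% ± 1.9 against 63.6% ± 3.5), and chromosome 18, 29550137 to 29550173 (92.9% ± 3.0 against 80.5% ± 3.7). These 5 regions, which showed the 5 largest gains, also had 1.33 to 2.7 times as many reads in males as in females, above 1.326, the ratio exceeded by 2.5% of tested autosomal regions. A region of 42 CpGs on chromosome 7, at 31875320 to 31875847, was at 7.5% ± 1.0 in females and 0.3% ± 0.1 in males (SD, n = 16 each, adjusted p = 2.5e-24, 11560 reads per animal, male to female read ratio 0.94); it was chosen after its values were seen. The largest losses in females were at chromosome 14, 101201808 to 101201846 (30.7% ± 11.6 against 50.6% ± 12), chromosome 7, 62314827 to 62314860 (74.4% ± 9.1 against 89.7% ± 4.7), and chromosome 16, 32181478 to 32181641 (48.6% ± 4.4 against 60.4% ± 8.1). Losses of 11.3 and 11.2 points were found at chromosome 4, 165174960 to 165175247, and chromosome 8, 45253502 to 45253626. With family as a block 17 regions were called, 12 higher and 5 lower. Among the 35, 12 of the 14 gains and 3 of the 21 losses stayed called. Of the 5 losses named here, that at 62314827 on chromosome 7 was called with the block (adjusted p = 0.0189), and the other 4 were not (adjusted p from 0.0981 to 0.158). Without the 6 THC female libraries with many thinly covered cytosines 13 were called, all higher in females.

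**Figure D3:**
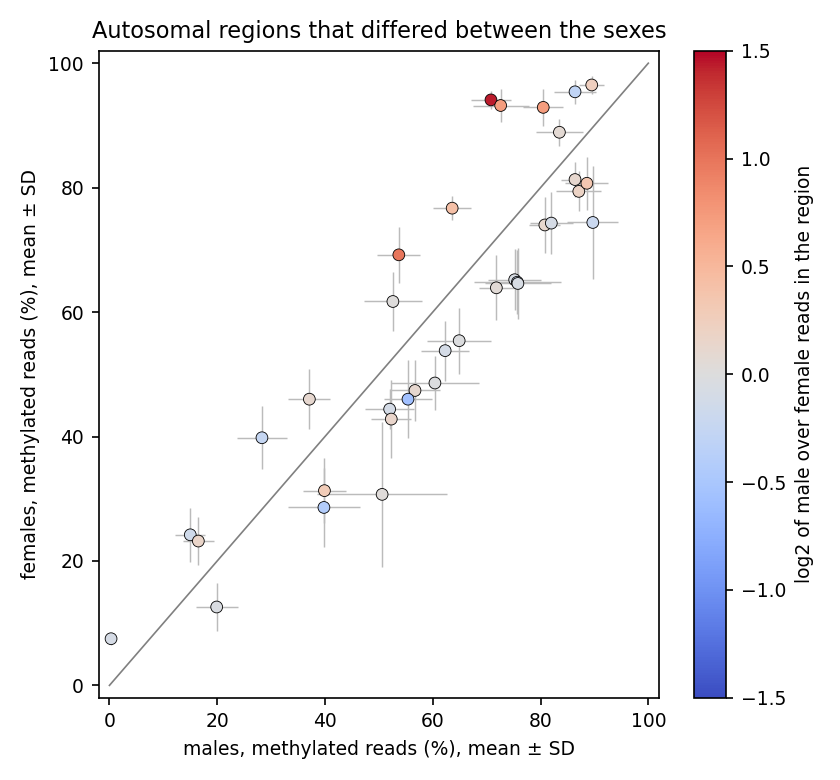
Mean methylation in 16 females (vertical axis, %) and 16 males (horizontal axis, %) of the 35 autosomal regions called for sex, with SD as grey bars, coloured by the log2 ratio of male to female reads; the line marks equal levels. Points above the line are the 14 regions higher in females, and the 5 with the largest gains have the redder colours of a ratio of 1.33 or more.

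Families within a line were compared to see how much methylation varies between families of the same exposure. Of 120968 regions, 133 differed between families, with a median range of 25.8 points between the highest and lowest family mean, against 7.3 points over all tested regions. The regions named here were chosen after their values were seen. The smallest adjusted p was found on chromosome 2, at 68406318 to 68406359 (4 CpGs), where family means ran from 61.3% in family 20 to 89.2% in family 26, and on chromosome 6, at 122915383 to 122915440 (3 CpGs), from 77.9% in family 18 to its highest in family 27. On chromosome 10, the region at 55792610 to 55792712 (11 CpGs) ran from 0.0% in family 18 to 39.9% in family 22, which was a single animal. A CpG ranging over more than 50 points between animals was present in 89.5% of the 133 regions and in 36.1% of the other tested regions. This difference follows in part from the choice of regions, since both measures take up spread between animals. With such CpGs left out, 13 of 98915 regions differed between families. Regions of 10 or more CpGs were fewer among the 133 than among tested regions (6.8% against 17%, Fisher's exact test, two-sided, adjusted p = 0.00337), as were unmethylated regions (11.3% against 25.8%, adjusted p = 0.000789). Intermediate regions were more frequent among the 133 (43.6% against 28.1%, Fisher's exact test, two-sided, adjusted p = 0.000852).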

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

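The tests on read ratios and on leaving out other females, the linkage value without its closest pair, and the fits without particular libraries or with the coverage share, were chosen only after the results were seen. Chance flags about 1 in 20 groups by distance from the other samples; 11 flags arose in 64 groups.

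The 6 thinly covered THC female libraries bear on the autosomal sex differences. The 35 called regions exceeded the highest of the other assignments of sex within lines (1 of 100 assignments gave as many, highest other 3), which excludes chance for assignments that ignore families. Without those 6 libraries 0 regions were lower in females; leaving out 6 of the other females called more in 99 of 99 draws, but each draw keeps all 6 among fewer females and is compared with a count of 0, so this decides nothing. With the share as a covariate 20 of the 35 stayed called, 13 of the 14 gains and 7 of the 21 losses. Without those 6 libraries 10 of the 14 gains and 0 of the 21 losses stayed called. These values argue against the coverage of these libraries as the cause of most gains. For the losses they leave it open. Of the losses, 1 of 21 had a male to female read ratio outside 0.679 to 1.326, the central 95% of tested regions. Sex-chromosome copies placed on autosomes stay open for the losses, since a copy on X could shift the ratio by less than that. Such copies also stay open for the gains, where 5 of 14, those with the largest gains, had excess male reads (one-sided binomial p = 1.6e-05). At these 5, unmethylated extra reads alone would put males at 34.8% to 57.8%. The measured male levels, 53.7% to 80.5%, lay above that value and below the female level in each region. Extra reads that are partly methylated could thus give the whole difference there, which was not tested. Sex itself stays open as untested.

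The 13 exposure regions called with animals as replicates, 7 of them on chromosome 10, exceeded other splits of the animals (1 of 100 gave as many, highest other 5). They exceeded most splits of whole families (2 of 100 gave as many, highest other 28), and what gave 28 was not tested. On the 8489 regions at an unadjusted p under 0.05, 6 of 100 splits of whole families gave as many (highest other 9469). Chance is thus less likely for the number called alone, but not excluded. CpG variants within the regions could account for part of them. Without variant-like CpGs 4 of 12 measured regions held, and the other 8 lay between -1.9 and 2.4 points. This share lies on the limit set beforehand for variants as the cause, so the test does not decide. However, 1 of the 4, on chromosome 9, held no such CpG, so among regions the filter could change the share lies below that limit. With the coverage share as a covariate 9 of 13 stayed called, which does not decide either. The 5 regions on chromosome 10 under 20 Mb may share a haplotype that differs between the lines: their mean absolute correlation within groups was 0.248, at percentile 96.9 of sets from different chromosomes and above the 95 set beforehand, but at percentile 92.6 without the closest pair (r = 0.67), on which it rests. Parental exposure stays open as untested. Without the 6 thinly covered libraries, which leaves 2 THC females, 1 of the 13 was called, while all 13 kept their sign and differences of -16.1 to -6.1 and 6.7 to 17 points. The remaining animals were among those on which the 13 were chosen. Neither the lost calls nor the kept differences therefore decide about coverage.

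In females, 10378 regions had an unadjusted p under 0.05 for exposure, and 2 of 100 splits of the families gave as many (highest other 12232). This lies under the limit set beforehand. As another split gave more, and several such counts were examined, chance is less likely for that number but not excluded. The 6 thinly covered libraries are all THC females, so their coverage and exposure are nearly confounded. Across the regions in question, the slope of methylation on the coverage share among males correlated with the female THC minus VEH difference at 0.191 (0.091 over all regions, which are not independent replicates), between the 0.05 and 0.2 set beforehand. Without those libraries 5929 regions had such a p, but only 2 THC females are then left, and with the coverage share as a covariate 11446 had. A coverage effect and an effect of parental THC cannot be told apart in females.

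With animals as replicates, the THC minus VEH difference differed between the sexes at 4 regions. The female minus male difference was -41.4 points on chromosome 12, -21.6 on chromosome 10, -21.4 on chromosome 11 and -18.9 on chromosome 1. Of 100 assignments of sex, 1, the real one, gave as many (highest other 2). However, 7 of 100 gave as many as the 7985 regions at an unadjusted p under 0.05 (highest other 9438). These assignments ignore families, so chance is less likely for the number called alone but not excluded. With family as a block 0 were called (smallest adjusted p 0.207), as was the case at 20 reads, with the coverage covariate and without the 6 libraries. Other values stood apart within groups of animals. VEH male 26_4 had 38.7% methylated reads over all CpGs (next 34.8%), 1.40% in unmethylated regions, 0.043% of bases that were neither C nor T and 216.6 × 10⁶ cytosine calls (next 267.7). VEH female 16_13 and THC female 25_6 had the highest X levels of their groups, 30.7% and 31.3%, and the highest shares of other bases, 0.086% and 0.049%. VEH male 20_6 had 21.9% of cytosines under 10 reads. Among exposure regions, THC family 25 was lowest on chromosome 7 at 77.5% (next 83.3%), and THC family 5 was lowest on chromosome 9 at 63.1% (next 67.0%). In data outside the comparisons, 1 X region was called for exposure in males, at 68904947 to 68904987, with 99.6% ± 0.5 in THC and 94.4% ± 1.4 in VEH families (SD, n = 5 each, adjusted p = 0.0333). Unplaced sequence held 11 regions called for sex. Mitochondrial CpGs, at 0.087% to 0.218% methylated reads, were 0.052 points higher in THC than VEH males (0.154% against 0.102%, n = 5 families each, exact permutation test, two-sided, p = 0.0159, adjusted p = 0.0636).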

How the results depend on the processing

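Fits without particular libraries and with the coverage covariate, global levels without single families, and sexes paired within family, were chosen after seeing the data. Without single families, the exposure difference over all CpGs ran from -0.53 points (without family 27) to 0.243 (without family 5), against -0.221 in the main fit. In males it ran from 0.595 (without family 27) to 1.538 (without family 5), against 0.981. In females it ran from -2.484 (without family 26) to -1.504 (without family 16), against -2.047. None of these exposure differences passed the adjusted threshold. The exposure count of 0 held at 20 and 30 reads, for CpGs in all 32 animals, at 50 and 200 bp joining, with plus-strand calls, without variant-like CpGs, with unmoderated dispersion, with no or a 10-point minimum difference, in limma and edgeR on families, and in the added fits. It rose to 13 with animals as replicates, 8 of them intermediate, a level at which a 5-point difference is more easily met than near 0%, to 4 in limma with family as a random block, and to 6 of 1287349 for single CpGs, all lower in THC. Leaving out a family gave 0 to 1, with 1 region without family 20. In females it was 1 with animals as replicates and 0 to 3 when a family was left out, with 3 without family 26; in males it was 2 and 0 to 4, with 4 without family 3. The cause of these changes was not tested. The interaction count of 4 was 0 with family as a block, 0 without the 6 THC female libraries, 0 with the coverage covariate and 2 without 24_8 and 19_5. At 20 reads it was 0, with the region on chromosome 10 at -21.6 points (adjusted p = 0.0522), that on chromosome 11 at -18.8 (adjusted p = 0.137) and the other 2 not measured. Autosomal sex regions numbered 17 with the block, 13 without the 6 libraries, 28 with the covariate, 30 without 24_8 and 19_5, and 48 at 20 reads (16 higher and 32 lower in females), and X regions stayed within 1109 to 1214. Family regions fell from 133 to 13 without variant-like CpGs, a filter on spread between animals, with 98915 of 120968 regions left to test. The sex difference in intermediate regions was -1.31 points as an unweighted mean, -1.07 without the 6 libraries, -1.48 without 24_8 and 19_5 and -1.38 with sexes paired within family, none past the adjusted threshold; the cause was not tested. Of 216 values of the 13 exposure regions under alternatives that can change them, most from leaving out 1 family, 213 kept their sign. The 13 were chosen for a difference in these same data, so fits that keep nearly all of the data could hardly reverse a sign. All 3 reversals came from leaving out variant-like CpGs or from plus-strand calls. Without variant-like CpGs 6 of the values that kept their sign lay between -1.9 and 2.4 points. Without variant-like CpGs the region on chromosome 10 at 14232978 was at -0.1 points and that on chromosome 5 at 154732516 at 1.5, and with plus-strand calls, which measured 9 of the 13, the former was at -2.2 and that on chromosome 10 at 12847742 at 0.8 (6.4 with both strands). Gene lists were not run, and features of regions called for exposure have no main value, as 0 were called with families as replicates. Depth limits which regions were measured: of 127520 regions tested for exposure, the count fell to 119681 at 20 reads and 112718 at 30.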

Other observations

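Of X regions under 5% in males, 722 of 757 had a female mean between 10% and 40%. The number of regions differing between families, 133, was exceeded by no other assignment of family numbers within lines (1 of 100 gave as many, highest other 124). However, 21 of 100 gave as many as the 10179 regions at an unadjusted p under 0.05 (highest other 15094). Chance is thus less likely for the number called alone, and what gave 124 in another assignment was not tested. For exposure with families as replicates, 11 of 100 splits gave as many regions at an unadjusted p under 0.05 as the real 7566 (highest other 9501), so chance was not excluded; in males it was 37 of 100 for 7571 (highest other 9485). For the X chromosome, 1 of 100 assignments of sex gave as many as 1209 regions (highest other 1), which excludes chance.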
